A study of Mus musculus with 7 samples.

How the data were processed

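RNA was sequenced from natural killer (NK) cells of mouse spleen, taken directly ex vivo. Per the labels, the cells were sorted as CD45+ CD3- NK1.1+ NKp46+ CD49b+, from 4 Hhex knockout samples (Hhex KO) and 3 Cre control samples of the C57BL/6 strain. RNA was extracted with a column kit, libraries were made with a directional (strand-marking) kit, and single-end reads of 75 bp were taken on an Illumina instrument, per the labels' protocols. The submitters' processing notes name STAR, featureCounts and the mm10 genome build, without versions. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes may have been shared out in a way that cannot be traced.

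The authors deposited a table of raw read counts per gene, with no normalization, 53379 genes and 1 column for each of the 7 libraries. Each column was matched to its sample by the title in the labels, and 0 columns of other values were left unused. No row was without a gene. Of the gene identifiers, 99.8% matched the gene name table without their version number and 94.8% with it. Coordinates are those of the GENCODE M21 annotation on GRCm38, the assembly also called mm10, and are 1-based.

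Total counts ranged from 10589915 to 18456404 per library. Replicate libraries were compared by a chi-square test of their counts over genes. The chi-square per degree of freedom ranged from 11.2 to 79.7 within groups, far above sampling noise, so each library was counted as 1 replicate. In the deposited table, Hhex KO replicate 4 carries the sample number 95 and the others numbers from 20 to 28; whether it belongs to another batch is not given in the sources used here. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples, which may in part be technical. With so few libraries, an exact permutation test of 4 against 3 cannot go below p = 0.0286.

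Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by edgeR's filter on expression by group (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and the quasi-likelihood F test with robust dispersions compared Hhex KO with Cre control with no covariate. Adjusted p-values are Benjamini-Hochberg values over the 12161 genes tested, and a gene was called when its value was below 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM are counts-per-million values of the TMM-scaled library size and are given as mean ± SD.

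Before the data were examined, 31 gene lists were fixed from textbook knowledge, and the 30 with at least 3 tested members were tested with camera (preset inter-gene correlation of 0.01, two-sided) and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. For each list, the members past 0.05 are counted over all genes tested and, separately, adjusted over the list alone. The genes to be named were also fixed by rule: Hhex and Bcl2l11; the 12 higher and the 12 lower genes with the largest fold change among those past 0.05 with an average log2 CPM of at least 2 and groups that do not overlap in CPM, leaving out predicted, clone and pseudogene names; and up to 4 members with the smallest p from each list that is described. Which lists are described, and the genes that are named beyond this rule because 5 or fewer members of a list were called, were chosen after the values were seen; the alternatives were not run for the latter. The values of 1 gene that the rule names are not reported here. Families whose near-identical members can share reads (Klra, Klrc, Bcl2a1, the globins) are given as uncertain.

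The procedure was tested on simulated counts of the 12161 genes, drawn from the means, dispersions and library sizes of this comparison, with 200 genes changed. A list of 20 further genes was raised by 1.5-fold. The counts of recovered genes that follow leave these 20 out, while the total of calls includes any of them. The edgeR test called 2 of 67 genes changed by 1.5-fold, 37 of 67 changed by 2-fold and 58 of 64 changed by 4-fold in the right direction, and 3.92% of its calls were unchanged genes. The simulated genes vary independently of each other, so the simulation does not check the list tests, which depend on the correlation between genes. It also holds no structure of the libraries apart from the groups, so the 3.92% need not hold in the real counts. At this depth and spread, changes of 1.5-fold were therefore mostly missed, and many of 2-fold.

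The alternatives tried were RLE and upper-quartile scaling, no filter and a stricter filter (at least 10 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample quality weights, a block for the replicate number on the 6 libraries numbered 1 to 3, and leaving out each library. A model with the level of nuclear-retained RNA as a covariate was added after the data were seen. Tests of gene location and of pseudogene sequence used Python 3.11.15, SciPy 1.17.1 and BLAST+ 2.17.0.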

Results

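The deposited counts describe the transcriptome of sorted splenic NK cells, the innate lymphocytes that kill target cells without prior priming, in 4 Hhex KO and 3 Cre control libraries. Hhex encodes a homeobox transcription factor, and Bcl2l11 encodes BIM, a pro-apoptotic protein of the BCL-2 family that the series title names. The single comparison of the design asks how loss of Hhex changes gene expression in NK cells. Total counts were 13433133, 11482273 and 18456404 in Cre control replicates 1, 2 and 3, and 14857855, 18414034, 17730766 and 10589915 in Hhex KO replicates 1, 2, 3 and 4. Unless another tool is named, adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 Hhex KO and n = 3 Cre control, and log2 fold changes are Hhex KO over Cre control with their standard errors.

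The targeted gene, Hhex (ENSMUSG00000024986.11, chromosome 19, 37434810 to 37440731), was lower in every Hhex KO library but still read. Its level was 96.1, 95.6 and 93.5 CPM in Cre control replicates 1, 2 and 3, and 58.0, 56.5, 54.2 and 64.8 CPM in Hhex KO replicates 1, 2, 3 and 4. The log2 fold change was -0.70 ± 0.10 (adjusted p = 0.00768). Counts over the whole gene do not show which exons the remaining reads cover. Bcl2l11 (ENSMUSG00000027381.16, chromosome 2, 128126038 to 128162547) rose in all 4 Hhex KO libraries, from 155 ± 11.9 CPM (SD, n = 3) to 293 ± 42.9 CPM (SD, n = 4), with a log2 fold change of 0.92 ± 0.15 (adjusted p = 0.0123). The libraries did not overlap, at 144 to 168 CPM in Cre control and 230 to 327 CPM in Hhex KO. Without 1 control library the call of Bcl2l11 was lost, at an adjusted p of 0.0793, 0.0635 and 0.0532 without replicates 1, 2 and 3. That of Hhex was lost without Cre control replicate 1, at 0.0516.

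Of 12161 genes tested, 326 rose and 228 fell in Hhex KO. With all 7 libraries kept, DESeq2 gave 625 higher and 469 lower genes, limma-voom with sample quality weights 1541 and 1323, the nuclear-RNA covariate 1218 and 1085, and the stricter filter 186 and 183. Another split of the libraries into 4 and 3 gave 965 genes in all, against 554 for the real groups. At least 2-fold changes made up 243 of the higher and 108 of the lower genes. The groups did not overlap in CPM for all 554 called genes and for 19.3% of all tested genes. Over all splits into 4 and 3 that share averages 5.71%. Its spread between splits was not measured, so the difference does not exclude chance. Leaving out 1 library at a time moved the counts by more than 1.5 times in most cases. They were 91 higher and 50 lower genes without Cre control replicate 1, 153 and 82 without Cre control replicate 2, 95 and 57 without Cre control replicate 3, 189 and 108 without Hhex KO replicate 3, and 527 and 291 without Hhex KO replicate 4, whose sample number, 95, lies apart from those of the others, 20 to 28, so that another batch is not excluded. Without Hhex KO replicate 2 there were 225 and 151.

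The 12 higher genes named by the rule had log2 fold changes of 2.98 to 5.51. Cxcr6 (ENSMUSG00000048521.8, chromosome 9, 123806475 to 123811760), a chemokine receptor of tissue-resident lymphocytes, went from 3.91 ± 1.35 CPM (SD, n = 3) to 175 ± 34.4 CPM (SD, n = 4), a log2 fold change of 5.51 ± 0.29 (adjusted p = 3.83e-05). Nrp2, a neuropilin, rose by 4.36 ± 0.16 on the log2 scale, to 47.0 CPM from 2.26 CPM. Gcnt2, a glycosyltransferase, rose by 4.15 ± 0.20, and AA465934 by 4.06 ± 0.27. Fam184b (3.39), Cd163l1 (3.39), the water channel gene Aqp9 (3.37), Zdhhc14 (3.29), Gramd3 (3.21), the ADP-ribosyltransferase gene Art2b (3.09), the death receptor gene Tnfrsf25 (3.02) and Tmem176a (2.98) followed in log2 fold change. Gramd3 was the most abundant of these, at 202 ± 33.6 CPM (SD, n = 4) against 21.8 ± 2.80 CPM (SD, n = 3). Cd163l1 was no longer past 0.05 without Cre control replicate 3 (adjusted p = 0.0585).

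Among the lower genes, Baiap3 (ENSMUSG00000047507.12, chromosome 17, 25242659 to 25256364), which encodes a protein linked to vesicle trafficking, was almost absent from Hhex KO. Its counts were 2932, 2108 and 3519 in Cre control and 4, 2, 2 and 1 in Hhex KO, and the summed counts scaled by library size gave a ratio of 1346 (95% exact binomial interval 709 to 2945, which covers counting error only). Sdc4, a heparan sulfate proteoglycan, fell by 3.32 ± 0.21 on the log2 scale, Tanc1 fell by 3.29 ± 0.21 and Cdh22, a cadherin, fell by 2.56 ± 0.16. The chemokine gene Ccl4 went from 612 ± 181 CPM (SD, n = 3) to 105 ± 48.4 CPM (SD, n = 4), a log2 fold change of -2.54 ± 0.39. Slfn8 (-2.47), the inhibitory receptor gene Cd300lf (-2.45), Vegfa (-2.32), Rgs16 (-2.32), Sfxn2 (-2.21), Rgs1 (-2.20) and the tight junction gene Tjp1 (-2.14) were the other lower genes named by the rule. With no filter on low counts, Ccl4, Slfn8, Vegfa and Rgs1 were no longer past 0.05 (adjusted p 0.0513 to 0.23). Rgs1 was not past it with the stricter filter (adjusted p = 0.0566) or the nuclear-RNA covariate (0.0646). Calls were lost for Ccl4, Slfn8, Vegfa, Rgs16 and Rgs1 without Cre control replicate 1 (adjusted p 0.0573 to 0.185), Slfn8 and Rgs1 without Cre control replicate 2 (adjusted p 0.0615 to 0.077). Those of Slfn8, Vegfa, Rgs16 and Rgs1 were lost without Cre control replicate 3 (adjusted p 0.0646 to 0.14). Leaving out Hhex KO libraries ended calls for Slfn8 without Hhex KO replicate 1 (adjusted p 0.0554), Rgs1 without Hhex KO replicate 2 (adjusted p 0.111), Slfn8, Rgs16 and Rgs1 without Hhex KO replicate 3 (adjusted p 0.0554 to 0.13) and Rgs1 without Hhex KO replicate 4 (adjusted p 0.0752).

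**Figure D1:**
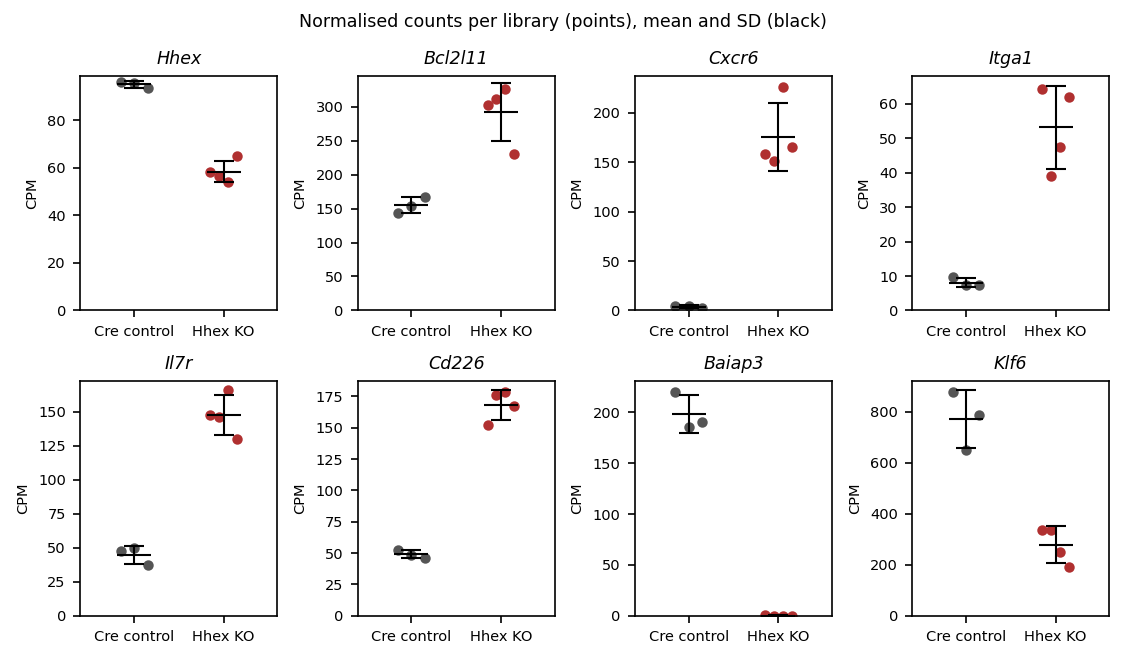
Each panel plots the normalised count of 1 gene (CPM, linear axis from 0) in the 3 Cre control and 4 Hhex KO libraries as points, with the mean and SD in black. The groups do not overlap in any panel; Baiap3 lies between 0.0886 and 0.259 CPM in Hhex KO.

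Genes associated with type 1 innate lymphoid cells (ILC1), tissue-resident relatives of NK cells, were higher as a group by camera. Of 20 tested members, 12 rose, 0 fell and 8 did not pass the test (14 higher and 1 lower adjusted over the list alone). Beside Cxcr6 and Tmem176a, they included Itga1, the CD49a integrin chain, at 53.2 ± 12 CPM (SD, n = 4) against 8.09 ± 1.37 CPM (SD, n = 3), and Il7r, the interleukin-7 receptor chain, at 148 ± 14.7 CPM (SD, n = 4) against 44.9 ± 6.80 CPM (SD, n = 3). Camera gave the list an adjusted p of 1.8e-31, and adjusted p = 0.130 with an estimated correlation, so the list call does not hold there. The same is true of the other 10 lists called by camera. With fry the list was past 0.05 (adjusted p = 0.0108), as were immature NK markers (0.0415) and T cell markers (0.038). The remaining lists called by camera were not past 0.05 with fry (adjusted p 0.0506 to 0.25). Markers of immature NK cells were higher by camera (adjusted p = 1.99e-05, and adjusted p = 0.474 with an estimated correlation), with 8 of 24 members higher and 2 lower (11 higher and 3 lower adjusted over the list alone). The lower members were Kit, with a log2 fold change of -1.42, and Kcnj8. Itga1 and Il7r are also on this list, as are Slamf6, with a log2 fold change of 0.99 ± 0.12, and Thy1, at 0.97 ± 0.14. Markers of mature NK cells were lower by camera (adjusted p = 0.00624, and adjusted p = 0.474 with an estimated correlation), although the members went both ways: 3 of 20 rose and 5 fell (3 higher and 11 lower adjusted over the list alone). Klrb1b, an NK1.1-family receptor gene, rose by 1.00 ± 0.12 on the log2 scale and Cx3cr1, a chemokine receptor of mature NK cells, rose by 1.00 ± 0.13, whereas Ly6c2 fell by 1.14 ± 0.23 and Cym fell by 0.63 ± 0.12. Cish was the other higher member, and Irf8, S1pr5 and Cma1 were the other lower members. Trafficking receptors were higher by camera (adjusted p = 0.00539, and adjusted p = 0.474 with an estimated correlation) with a median log2 fold change of 0.01. Among 24 members, 5 rose and 1 fell (6 higher and 4 lower adjusted over the list alone). The higher members were Cxcr6, Itga1, Cx3cr1, Gpr183 and S1pr1, and the lower member was S1pr5. S1pr1 rose by 1.02 ± 0.19 on the log2 scale. The camera call of this list was lost with limma-voom (adjusted p = 0.22, and 0.119 with sample quality weights). Among the genes of these lists, calls were lost for Thy1, Cym, Ly6c2 and S1pr1 without Cre control replicate 1 (adjusted p 0.0625 to 0.0993), Cym, Ly6c2 and S1pr1 without Cre control replicate 2 (adjusted p 0.0869 to 0.117) and Thy1, Cym, Ly6c2 and S1pr1 without Cre control replicate 3 (adjusted p 0.06 to 0.113). They were also lost for Cym and Ly6c2 without Hhex KO replicate 1 (adjusted p 0.0507 to 0.0516) and Cym and Ly6c2 without Hhex KO replicate 3 (adjusted p 0.0638 to 0.0716).

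Other NK cell lists were not past 0.05 by camera, but single members moved. Of 37 NK receptors and adaptors, 3 rose and 0 fell (4 higher and 2 lower adjusted over the list alone). Cd226, the activating receptor DNAM-1, rose from 48.9 ± 3.20 CPM (SD, n = 3) to 168 ± 12 CPM (SD, n = 4), with Slamf6 and Klrb1b the others. Klrg1, an inhibitory receptor of mature NK cells, had a log2 fold change of -0.52 ± 0.13 (adjusted p = 0.0643). The camera adjusted p of the list was 0.573; its test and mean were above 0 and its median below. Of 43 NK-lineage transcription regulators, 3 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.399). Zfp683, which encodes Hobit, rose by 2.60 ± 0.28 on the log2 scale, Ahr rose by 1.21 ± 0.18 and Lef1 rose by 0.83 ± 0.13, while Klf6 went from 771 ± 113 CPM (SD, n = 3) to 279 ± 71.3 CPM (SD, n = 4). Nfil3, Irf8 and Klf2 were the other lower members. Of 23 cytotoxic effectors, 2 rose and 3 fell (2 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.234, and 0.0353 and lower without Cre control replicate 3). Gzmk, a granzyme, rose by 2.71 ± 0.20 on the log2 scale and Tnfsf10, the death ligand TRAIL, rose by 1.25 ± 0.19. Ccl4, Cst7 and Fasl, the Fas ligand, were the lower members, and Fasl fell by 1.05 ± 0.21. Of 27 genes of interleukin-15 and interleukin-2 signalling, 4 rose and 2 fell (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.874). Socs2 rose by 1.69 ± 0.16, Il2ra rose by 1.90 ± 0.29 and Cish rose by 0.80 ± 0.17, and the kinase gene Pim1 fell by 0.74 ± 0.13. Myc was the other higher and Dusp2 the other lower member. The mean of this list was 0.00023, with its median and test below 0. Of 17 FOXO targets, 4 rose (Bcl2l11, Il7r, S1pr1 and Tnfsf10) and 2 fell (Bcl6 and Klf2) (4 and 2 adjusted over the list alone; camera adjusted p = 0.165). With 1 library left out, calls ended for Fasl, Klf6, Ahr, Lef1, Pim1 and Cish without Cre control replicate 1 (adjusted p 0.0506 to 0.146), Lef1, Pim1 and Cish without Cre control replicate 2 (adjusted p 0.0541 to 0.143) and Tnfsf10, Fasl, Il2ra, Pim1 and Cish without Cre control replicate 3 (adjusted p 0.0585 to 0.119). The replicate block ended the call of Cish (adjusted p = 0.0515). The same held for Cish without Hhex KO replicate 1 (adjusted p 0.0584), Fasl and Cish without Hhex KO replicate 2 (adjusted p 0.0531 to 0.0602) and Fasl, Pim1 and Cish without Hhex KO replicate 3 (adjusted p 0.0554 to 0.06).

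Among genes of apoptosis, 1 of 9 tested pro-apoptotic BCL-2 family members, Bcl2l11, was past 0.05 over all genes with edgeR (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.473). Bmf had a log2 fold change of -0.95 ± 0.26 (adjusted p = 0.0805). It was past 0.05 and lower with DESeq2 (adjusted p = 0.0156), no filter (0.0453), limma-voom with sample quality weights (0.00719) and the nuclear-RNA covariate (0.0181). The log2 fold changes of the next members were, for Bik, 2.08 ± 0.70 near 1 CPM (adjusted p = 0.149) and, for Pmaip1, -0.33 ± 0.21 (adjusted p = 0.449). Bik was past 0.05 and higher with limma-voom with sample quality weights (adjusted p = 0.0251) and the nuclear-RNA covariate (0.0465). Of 6 pro-survival members, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.165, and 0.038 and lower with fry). The lower member was Bcl2a1b, which fell by 1.26 ± 0.28 but can share reads with near-identical copies and is uncertain. Mcl1 was at 563 ± 50.3 CPM (SD, n = 4) against 718 ± 12.4 CPM (SD, n = 3), with adjusted p = 0.155. It was past 0.05 and lower with DESeq2 (adjusted p = 0.0235), limma-voom with sample quality weights (0.0379) and the nuclear-RNA covariate (0.026). The log2 fold changes of Bcl2 (0.22 ± 0.14) and Bcl2l1 (-0.24 ± 0.16) were not past 0.05, although Bcl2l1 was with the nuclear-RNA covariate (adjusted p = 0.0374). Of 20 caspases and death receptor genes, Ripk3 rose by 0.71 ± 0.15 and the other 19 did not pass the test (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.905). Cflar had a log2 fold change of -0.43 ± 0.13 (adjusted p = 0.106) and Fas -0.56 ± 0.18 (0.138). Both were past 0.05 and lower with limma-voom with sample quality weights (adjusted p = 0.00911 and 0.0226) and the nuclear-RNA covariate (0.0118 and 0.0416). Cflar was so with DESeq2 too (0.0399). The median and test of this list lay below 0 and its mean above. Of 17 p53 targets, 0 rose and Btg2 fell (camera adjusted p = 0.449; 0 and 1 adjusted over the list alone). With fewer libraries, calls were lost for Bcl2a1b and Ripk3 without Cre control replicate 1 (adjusted p 0.163 to 0.174), Bcl2a1b and Ripk3 without Cre control replicate 2 (adjusted p 0.0787 to 0.15) and Bcl2a1b and Ripk3 without Cre control replicate 3 (adjusted p 0.0787 to 0.138). Leaving out Hhex KO libraries, calls ended for Bcl2a1b and Ripk3 without Hhex KO replicate 1 (adjusted p 0.0564 to 0.0614), Bcl2a1b and Ripk3 without Hhex KO replicate 2 (adjusted p 0.0666 to 0.0862), Bcl2a1b and Ripk3 without Hhex KO replicate 3 (adjusted p 0.0748 to 0.0756) and Bcl2a1b without Hhex KO replicate 4 (adjusted p 0.0506).

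Proliferation genes were higher by camera. All 30 members had positive log2 fold changes, with a median of 1.66, and 8 passed the test (22 adjusted over the list alone). Birc5, which encodes survivin, rose by 2.04 ± 0.37 on the log2 scale, Tk1, thymidine kinase, rose by 1.97 ± 0.33, Ccnb1, cyclin B1, rose by 1.72 ± 0.28 and Cdk1 rose by 1.68 ± 0.31. Camera gave an adjusted p of 5.46e-18, and adjusted p = 0.474 with an estimated correlation. The library levels spread widely: Mki67, the Ki-67 gene, was at 223 CPM in Hhex KO replicate 1, at 32.5 to 55.1 CPM in the other Hhex KO libraries and at 7.79 to 26.3 CPM in Cre control, and did not pass the test (adjusted p = 0.109). With edgeR 0 of the 5 tested CDK inhibitors passed 0.05 over all genes (3 at an unadjusted p under 0.05; 1 higher and 2 lower with DESeq2, and as many adjusted over the list alone), with a camera adjusted p of 0.412. Cdkn2c had a log2 fold change of 0.83 ± 0.21, Cdkn2d -0.56 ± 0.15, Cdkn1a -1.09 ± 0.34 and Cdkn1c -0.35 ± 0.25. Without Hhex KO replicate 4, Cdkn2c (adjusted p = 0.0209) and Cdkn1a (0.0453) were past 0.05. Cdkn2a was too low to be tested, with 0 counts in each Cre control library and 6, 7, 1 and 1 counts in Hhex KO. Without 1 control library, calls ended for Ccnb1, Birc5 and Cdk1 without Cre control replicate 1 (adjusted p 0.0511 to 0.0889) and Ccnb1, Tk1, Birc5 and Cdk1 without Cre control replicate 3 (adjusted p 0.0571 to 0.102).

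Immediate-early and dissociation stress genes were lower by camera (adjusted p = 2.47e-09, and adjusted p = 0.474 with an estimated correlation). Of 33 members, 0 rose and 5 fell (0 and 13 adjusted over the list alone), and the median log2 fold change was -1.09. Jund, an AP-1 subunit, fell by 1.53 ± 0.27 on the log2 scale, Btg2 fell by 1.38 ± 0.24, Nfkbia fell by 1.28 ± 0.25 and Ier5 fell by 1.03 ± 0.17. Levels varied between Hhex KO libraries: Fos was at 121, 238, 57.3 and 5.76 CPM in replicates 1, 2, 3 and 4, against 403 to 571 CPM in Cre control, and was not past 0.05 (adjusted p = 0.237). Cytosolic ribosomal protein genes were higher by camera (adjusted p = 4.43e-08, and adjusted p = 0.681 with an estimated correlation), but 0 of 45 passed 0.05 as single genes with edgeR (0 adjusted over the list alone, 17 at an unadjusted p under 0.05, and 5 with DESeq2). Rplp0 (0.69 ± 0.22), Rps6 (0.53 ± 0.16), Rpl15 (0.52 ± 0.17) and Rpl10a (0.51 ± 0.16) had the smallest p. These 4 genes passed with DESeq2, with limma-voom with sample quality weights and with the nuclear-RNA covariate, and Rps6, Rpl15 and Rpl10a did so without Hhex KO replicate 1 (adjusted p 0.0269 to 0.0447). Nuclear-retained RNAs differed within the groups too: Malat1 was at 138 and 155 CPM in Hhex KO replicates 3 and 2, and at 650 and 918 CPM in Hhex KO replicates 4 and 1. With edgeR, 0 of 35 interferon-stimulated genes (camera adjusted p = 0.338), 0 of 19 glycolysis genes (0.338), 0 of 35 oxidative phosphorylation genes (0.451) and 0 of 7 mitochondrially encoded genes (0.874) passed 0.05, over all genes and adjusted over the list alone. At an unadjusted p under 0.05 there were 5, 5, 0 and 0, and DESeq2 called 1, 2, 0 and 0. By camera the glycolysis list was higher without Hhex KO replicate 4 (adjusted p = 0.0374), with the replicate block (0.0192) and with limma-voom with sample quality weights (0.00946). The oxidative phosphorylation list was higher without Hhex KO replicate 1 (0.0218) and with those weights (0.000585). Immediate-early calls were lost for Ier5, Btg2, Jund, Nfkbia and Rgs1 without Cre control replicate 1 (adjusted p 0.0639 to 0.185), Jund and Rgs1 without Cre control replicate 2 (adjusted p 0.0511 to 0.077) and Btg2, Jund, Nfkbia and Rgs1 without Cre control replicate 3 (adjusted p 0.0559 to 0.14). In the knockout group they were lost for Nfkbia and Rgs1 without Hhex KO replicate 2 (adjusted p 0.0588 to 0.111), Nfkbia and Rgs1 without Hhex KO replicate 3 (adjusted p 0.0775 to 0.13) and Rgs1 without Hhex KO replicate 4 (adjusted p 0.0752).

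**Figure D2:**
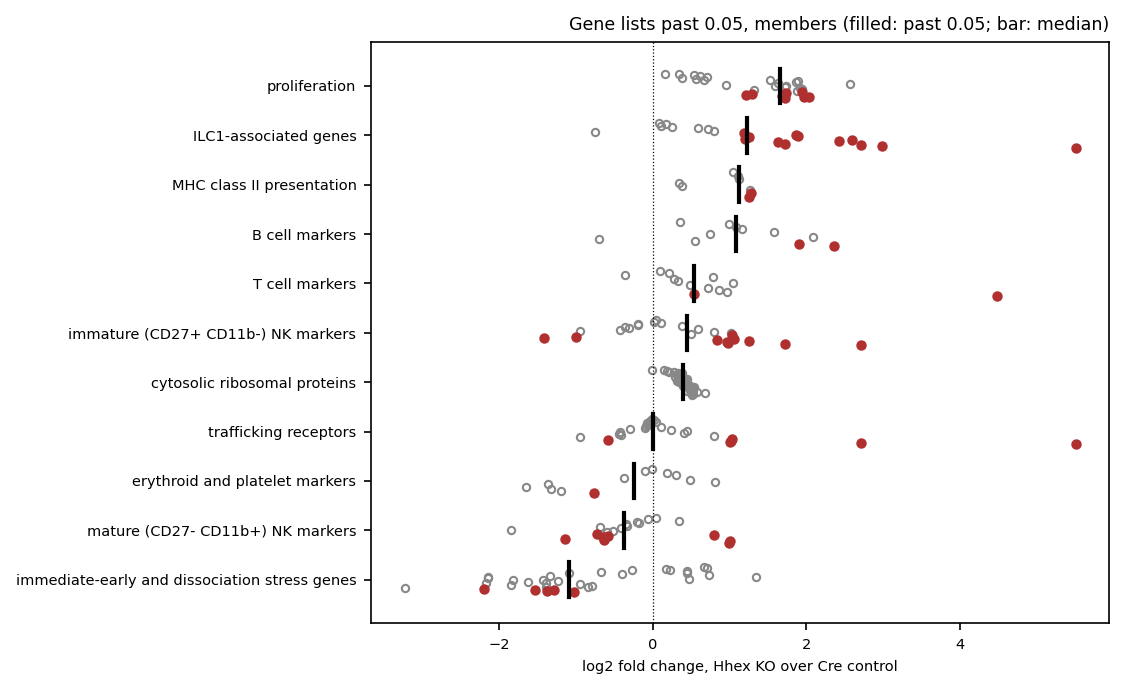
Points are the log2 fold changes (Hhex KO over Cre control) of the tested members of the 11 gene lists past 0.05 by camera, filled where the gene itself is past 0.05, and bars are list medians. The ILC1-associated list has 12 filled points and the ribosomal list 0.

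Markers of other cell types were measured in the same libraries. T cell markers were higher by camera (adjusted p = 5.47e-05, and adjusted p = 0.474 with an estimated correlation), with 2 of 13 members past 0.05 (7 adjusted over the list alone). Themis, a regulator of T cell selection, was at 6.36 ± 1.69 CPM (SD, n = 4) against 0.275 ± 0.110 CPM (SD, n = 3), and Trbc2, a T cell receptor constant segment, had a log2 fold change of 0.54 ± 0.12. Trbc2 was not past 0.05 with no filter (adjusted p = 0.0524) or with the replicate block (0.0536). Cd3d (0.97 ± 0.27) and Cd3e (0.87 ± 0.29) were not past 0.05, but were without Hhex KO replicate 4 (adjusted p = 0.0409 and 0.0197). B cell markers were higher by camera (adjusted p = 0.0113, and adjusted p = 0.681 with an estimated correlation), with 2 of 11 past 0.05 (2 adjusted over the list alone). Cd22, an inhibitory receptor of B cells, was at 60.4 to 88.9 CPM in Hhex KO and 10.1 to 19.4 CPM in Cre control, and Cd79b rose by 1.90 ± 0.39. Ighm (0.55 ± 0.18) and Bank1 (-0.69 ± 0.47) were not past 0.05, but Ighm was without Hhex KO replicate 4 (adjusted p = 0.0152) and Bank1 was, and lower, without Hhex KO replicate 1 (0.0319). Of 8 MHC class II presentation genes, 2 rose (2 adjusted over the list alone), H2-Ob by a log2 fold change of 1.25 ± 0.23 and H2-Oa by 1.28 ± 0.30. H2-Ab1 (1.27 ± 0.76) and H2-DMb1 (0.38 ± 0.23) were not past 0.05; camera gave this list an adjusted p of 0.0271, and adjusted p = 0.681 with an estimated correlation. Camera calls were lost for the B cell list without Cre control replicate 3 (adjusted p = 0.0844) and Hhex KO replicate 1 (0.143), and for the MHC class II list without Cre control replicate 1 (0.0745) and Hhex KO replicates 1 (0.143) and 2 (0.0788). With limma-voom the B cell list was not past 0.05 either (0.055, and 0.0971 with sample quality weights), nor were Cd79b (0.0522) and H2-Oa (0.0539). Erythroid and platelet markers were lower by camera (adjusted p = 0.0113, and adjusted p = 0.681 with an estimated correlation), with 0 of 12 higher and 1 lower (0 and 5 adjusted over the list alone). Gp1bb, a platelet glycoprotein gene, fell by 0.77 ± 0.15, and Itga2b (-1.19 ± 0.35), Pf4 (-1.33 ± 0.42) and Gp9 (-1.64 ± 0.53) were not past 0.05, although Gp9 was without Hhex KO replicate 2 (adjusted p = 0.0424). The camera call was lost without Cre control replicate 2 (adjusted p = 0.0506), Hhex KO replicate 3 (0.0528) and Hhex KO replicate 4 (0.0905), with the stricter filter (0.337), with limma-voom with sample quality weights (0.119) and with the replicate block, which also leaves out Hhex KO replicate 4 (0.0786). With edgeR, 0 of 17 macrophage and dendritic cell markers (camera adjusted p = 0.331) and 0 of 11 neutrophil markers (0.165) passed 0.05, with 0 and 1 at an unadjusted p under 0.05, 0 and 1 adjusted over the list alone, and 0 and 1 with DESeq2. All 11 neutrophil markers had positive log2 fold changes, with a median of 2.22. Hhex KO replicate 2 stood apart: its mean log2 CPM over the list was 4.78, against -0.29 to 2.55 in the other libraries, and S100a8 was at 112 CPM there and at 3.90 to 18.3 CPM in the others. The neutrophil list was higher past 0.05 without Cre control replicate 2 (adjusted p = 0.0281), Hhex KO replicate 3 (0.0218) and Hhex KO replicate 4 (0.0149), with no filter (0.0321) and with the replicate block (5.97e-05). Without Hhex KO replicate 2 the macrophage and dendritic cell list was lower (0.000909). Of 3 mast cell and basophil markers, Kit and Cma1 fell (2 adjusted over the list alone; camera adjusted p = 0.0951). The sex-linked list had 1 tested gene, Xist, with a log2 fold change of 0.95, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 7 libraries. Marker calls were lost for Trbc2, Cd79b, H2-Ob, H2-Oa and Gp1bb without Cre control replicate 1 (adjusted p 0.0767 to 0.178), Trbc2, Cd79b, H2-Oa and Gp1bb without Cre control replicate 2 (adjusted p 0.105 to 0.164) and Trbc2, Cd79b, H2-Ob, H2-Oa and Gp1bb without Cre control replicate 3 (adjusted p 0.102 to 0.171). From the knockout group, calls ended for H2-Oa without Hhex KO replicate 1 (adjusted p 0.0881), Trbc2, Cd79b and H2-Oa without Hhex KO replicate 2 (adjusted p 0.0507 to 0.0907) and Trbc2, H2-Oa and Gp1bb without Hhex KO replicate 3 (adjusted p 0.0616 to 0.106).

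Of the 91 genes named by the rule, 64 were past 0.05, and 29 of these stayed past it under every alternative that tested them (Fam184b, Tjp1, Themis and Zfp683 were too low for the stricter filter), among them Cxcr6, Nrp2, Itga1, Il7r, Cd226, Gzmk, Zfp683, Socs2, Cd22, Themis, Baiap3, Sdc4 and Sfxn2. Calls of 35 were lost on leaving out a control library, of 15 on leaving out a Hhex KO library and of 7 in an alternative that kept all 7 libraries, and no call changed direction. Of the 27 named genes that were not past 0.05, 23 were past it in at least 1 alternative. With DESeq2 these included Klrg1 (adjusted p = 0.00547), Cflar (0.0399), Cdkn2c (0.00528), Cdkn2d (0.00901), Cdkn1a (0.0239), Cd3d (0.00919), Ighm (0.0412) and Itga2b (0.0207).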

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

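The tests on pairs of called genes, windows, pseudogenes per chromosome, pseudogene parents and heat-shock members were chosen after the results they rest on were seen; the others in this part were set after the patterns, but not their own results, were seen. In the 4 Hhex KO libraries, 94 values were examined for 1 library far from the rest, and 4 stood out, where chance gives about 4.7 (1 in 20). Cd300lf was at 2.95 CPM in Hhex KO replicate 3 and 4.66 to 4.81 CPM in the others. Trbc2 was at 175 CPM in Hhex KO replicate 3 and 137 to 144 CPM in the others. Bank1 was at 5.50 CPM in Hhex KO replicate 1 and 1.51 to 1.71 CPM in the others. Cish was at 29.5 CPM in Hhex KO replicate 2 and 20.2 to 21 CPM in the others.

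Baiap3 was nearly absent from Hhex KO, and 10 processed pseudogenes were higher in Hhex KO against 1 lower, 6 of the 10 on chromosome 6 (Fisher exact adjusted p = 0.000526 over 20 chromosomes). Segments of another strain carried in the knockout may account for part of this, and no test here excludes them: called genes made 774 pairs 0.5 to 5 Mb apart against 739 ± 45.9 (SD) when calls were shuffled (permutation p = 0.222, 10000 shuffles), no excess, but counted over all called genes, where a few segments would be diluted. The window of chromosome 17 from 20000001 to 25000000, next to Baiap3, held 12 called of 74 tested genes (exact binomial adjusted p = 0.066). That of chromosome 7 from 100000001 to 105000000, with Art2b, held 9 of 49 (0.0868). Its called genes included Gm35082 (0 CPM in Cre control and 7.06 CPM in Hhex KO) and Art2a-ps (0.018 and 4.91 CPM). Over all chromosomes, 12 called genes were below 0.3 CPM in Cre control and above 3 CPM in Hhex KO. The reverse held for 1 gene, Baiap3. On chromosome 11 from 80000001 to 85000000, with Slfn8, AA465934 and Ccl4, 8 of 52 were called (0.304). None of these windows passed 0.05, and the pairs leave out called genes closer than 0.5 Mb, so strain segments at these genes stay open. The called share of protein-coding genes on chromosome 6, 5.24% against 4.63% elsewhere (Fisher exact p = 0.527), decides nothing. Reads shared between a parent gene and its pseudogene also stay open. The 10 parents had a median log2 fold change of -0.11, 7 of them below 0 (exact sign test p = 0.344). A shift of a few CPM would be hidden in a parent as abundant as Lasp1 (601 CPM in Cre control), so that test decides little. Of the parents, 2 were lower past 0.05, both within that window of chromosome 17. Rnps1 went from 45.9 to 18.5 CPM while its pseudogene Gm9825 went from 0.303 to 15.5 CPM. Atp6v0c went from 17.0 to 4.56 CPM while Atp6v0c-ps2 went from 0.158 to 14.4 CPM. For these 2 pairs, reads moved from parent to pseudogene could give both changes. Loss of Hhex itself, which the design names, was not separated from these.

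Immediate-early genes were lower in Hhex KO by camera with the preset correlation (not past 0.05 with an estimated correlation, adjusted p = 0.474), with 5 of 33 members past 0.05 as single genes and the lowest list means in replicates 3 and 4. RNA recovery was not itself measured, and the mean log2 CPM of the nuclear-retained RNAs Malat1, Neat1 and Xist was taken as a stand-in. This mean was 8.21, 6.91 and 7.61 in Cre control replicates 1, 2 and 3. In Hhex KO replicates 1, 2, 3 and 4 it was 8.74, 6.41, 6.25 and 9.14, so this level did not separate the groups. As a covariate it could therefore hardly move the group difference. The list stayed lower with it by the same test (median log2 fold change -1.12, camera adjusted p = 0.000363), which decides nothing about RNA recovery as a cause. Handling before lysis cannot be told apart from the knockout, because the labels give no handling per library. The heat-shock members of the list had a median of 0.48, 8 of 9 above 0, and the other 24 members a median of -1.38, so the stress genes did not move as 1 block.

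Of the B and T cell markers, 2 of 11 and 2 of 13 were past 0.05 and higher in Hhex KO, although the sort excluded CD3+ cells and gated on NK1.1 and NKp46. Both lists were called by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.681 and 0.474), and the B cell list was not called without Hhex KO replicate 1 (adjusted p = 0.143) or with limma-voom (0.055). B cells as the source of Cd22 are argued against, and for Cd79b the source stays open. With the mean of the 11 tested B cell markers, these 2 included, as a covariate, Cd22 kept a log2 fold change of 2.33 ± 0.26 (2.36 ± 0.24 without it). Cd79b went to 1.47 ± 0.26 (1.90 ± 0.39 without it), with a largest adjusted p of 0.0303. In Hhex KO replicates 1, 2, 3 and 4, Cd79b was at 14.5, 8.25, 7.07 and 4.61 CPM. It followed the order of the list means there (3.62, 2.73, 1.49 and 0.86 log2 CPM). The abundant B cell transcript Igkc was at 54.5, 65.4, 7.36 and 0.974 CPM in Hhex KO replicates 1, 2, 3 and 4. It was at 5.30 to 23.8 CPM in Cre control. Cd22 was at 76.1, 65.5, 88.9 and 60.4 CPM in the same Hhex KO libraries and did not follow Igkc. Ms4a1 was at 9.91 CPM in Hhex KO replicate 1 and 1.09 CPM in replicate 2, so B cell reads in these libraries are not excluded. For the T cell markers the source, a change within NK cells included, stays open, since the list shares 2 members with other lists, and with the mean of its 13 tested members as a covariate Themis kept its call (3.68 ± 0.77, from 4.48 ± 0.39) and Trbc2 did not (0.28 ± 0.30, from 0.54 ± 0.12; adjusted p = 0.549), while Cd4 was at 0.118 and 0.0886 CPM and Cd8a at 0.177 and 0 CPM in Hhex KO replicates 3 and 4, where Themis was at 8.31 and 5.67 CPM.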

How the results depend on the processing

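The nuclear-RNA covariate was added after the data were seen; the other alternatives were set beforehand. No gene or list past 0.05 changed direction under any of them; in 27 cases a list past 0.05 in neither fit changed sign. Against 326 higher and 228 lower genes, RLE and upper-quartile scaling, no filter and limma-voom stayed within 1.5 times. The stricter filter, which tested 8613 genes, gave 186 higher genes, DESeq2 gave 625 higher and 469 lower, limma-voom with sample quality weights 1541 and 1323, and the nuclear-RNA covariate 1218 and 1085; the cause was not tested. Of the calls, 326 higher and 226 lower were among those of DESeq2, and the same numbers among those with the covariate. Leaving out 1 library gave 91 to 527 higher and 50 to 291 lower genes, with fewer samples in each fit. Over the libraries left out, the log2 fold change of Hhex ranged from -0.76 to -0.67 and that of Bcl2l11 from 0.86 to 1.01, so the lost calls came with little change in size. Against 11 lists past 0.05, fry gave 4, of which 3 are among the 11, an estimated correlation gave 0 (camera; 2 lists at an unadjusted p under 0.05), and the others gave 9 to 12; DESeq2 gives no list test. Same-numbered libraries did not all deviate together (correlations 0.15, 0.57 and -0.08), so a pairing by number is not shown. For number 2 it is not excluded. The value of 0.57 was the largest between the groups, and these libraries had the highest neutrophil list means of their groups (2.10 and 4.78). The replicate block on 6 libraries gave 499 higher and 275 lower genes, against 527 and 291 without the block. It gave 12 lists, and log2 fold changes of -0.76 for Hhex and 1.01 for Bcl2l11. Of the genes named by the rule, 3 calls were lost and 5 gained with the block against all 7 libraries. On the same 6 libraries, the block ended the calls of Trbc2 (adjusted p = 0.0536) and Cish (0.0515), while Bcl2a1b (0.0812 with the block) was not past 0.05 without it either (0.0506). In the simulated counts, 37 of 67 genes changed by 2-fold and 2 of 67 changed by 1.5-fold were called, so depth and spread limit the test at these sizes.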

Other observations

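The single genes of this paragraph, Eomes and Tbx21, the test of genes around Hhex, the count of splits over both directions and the fits with the nuclear-RNA covariate were chosen after the data were seen. Several called genes outside the lists and the naming rule changed strongly. Dtx4, which encodes a Deltex E3 ligase linked to Notch signalling, was at 4.12 ± 0.772 CPM (SD, n = 4) in Hhex KO and 0.122 ± 0.0904 CPM (SD, n = 3) in Cre control. Tlr1, a Toll-like receptor gene, was at 4.83 ± 0.862 CPM (SD, n = 4) against 0.298 ± 0.195 CPM (SD, n = 3). Nrp1, the paralog of Nrp2, rose by 2.35 ± 0.35 on the log2 scale. Nnt, a mitochondrial transhydrogenase gene known to be mutated in the C57BL/6J substrain, went from 29.1 ± 0.491 CPM (SD, n = 3) to 71.0 ± 16.2 CPM (SD, n = 4). The neighbouring imprinted genes Peg10 and Sgce fell by 1.89 ± 0.27 and 1.09 ± 0.21, and Vegfc fell by 1.30 ± 0.17, in the same direction as Vegfa.

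Of 17 tested neighbours of Hhex on chromosome 19, 3 rose and 1 fell (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.411, with a median below 0 and a mean above). The higher genes were Cep55, Plce1 and Hells, with log2 fold changes of 1.97, 2.93 and 1.42, and Exoc6 was lower at -0.50. Within 10 Mb of Hhex, 14 of 139 tested genes were called, 10.1% against 4.48% elsewhere (Fisher exact p = 0.00582, unadjusted). That test takes neighbouring genes as independent. The window of chromosome 19 from 35000001 to 40000000, which holds Hhex itself, had 5 called of 20 tested genes (exact binomial adjusted p = 0.298). Strain variants carried with the targeted locus could give an excess near Hhex. Regulation of nearby genes by Hhex stays open as well, and Cep55 and Hells are also cell-cycle genes, which were higher as a list by camera only with the preset correlation. Of 25 Polycomb components and partners, Pcgf6 rose by 0.69 ± 0.16 and Tle1 fell by 1.84 ± 0.29 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.898). Eomes, a transcription factor of the NK lineage, was at 772 ± 41.6 CPM (SD, n = 4) against 775 ± 59.0 CPM (SD, n = 3), with a log2 fold change of -0.01 ± 0.12, and Tbx21 differed by 0.05 ± 0.14, neither past 0.05.

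All 35 splits of the 7 libraries into 4 and 3 were fitted in the same way. For the 554 genes past 0.05 in either direction chance is not excluded, since 2 of the 35 splits gave as many and the highest other gave 965. The same holds for the 326 higher genes, where 2 splits gave as many and the highest other gave 747. Of the 228 lower genes, 1 split, the real one, gave as many in that direction and the highest other gave 218. However, the direction of a split other than the real one is arbitrary and the count of 747 is above 228, so chance is not excluded for them either. The split with these highest counts set Cre control replicates 1 and 3 and Hhex KO replicates 1 and 4 against the rest, and these are the 4 libraries with the highest nuclear-retained RNA (mean log2 CPM 7.61 to 9.14, against 6.25 to 6.91). It points to a structure of the samples apart from the groups. For the 11 gene lists, 13 splits gave as many and the highest other gave 14, so the number of lists past 0.05 by camera is no larger than chance gives. With the nuclear-RNA level as a covariate, 1 of 35 splits, the real one, gave 1218 higher genes, and the highest other gave 2. For lower genes 1 split gave 1085, and the highest other gave 8. However, this covariate divides the libraries in the same way as the split with the highest counts. It therefore takes up the difference of that split by its choice, so these counts do not exclude chance.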
